A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

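Genomic DNA of wild-type and eco1 mutant yeast at 0, 20 and 40 min after release from G1 arrest was sequenced as Nextera XT libraries, with 2 libraries per strain and time. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2 and Bowtie on the genome build sacCer3, and the notes give neither roles nor parameters for them. The authors deposited a single table with 12165 rows of 1000 bp and 22 columns. The 8 ratio columns, 1 per strain, time and replicate, are in log2 units as deposited. Their values fit log2 of reads scaled to library size (RPM) plus 1 in the later library over the same in the 0-min library, which was settled from the values, since the log base and pseudocount are not named in the headers. The 0-min library in the denominator is not named either, and was taken as that of the same strain and replicate. The deposited smooth columns were treated as a score, since they follow a running mean of the ratio columns on a larger scale. Their mean over mitochondrial rows was 1.49 to 1.51 times that of the ratio columns. Over nuclear rows their SD was 1.57 to 1.66 times that of the running mean. They were not used for any result.

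Whole reads of all 12 libraries were recovered from the ratios by finding, for each row, the read numbers of the 3 libraries of a strain and replicate that give both ratios. In simulated data 3000 of 3000 windows were recovered exactly. In the data, all 12165 rows had a solution in each strain and replicate, and that with the fewest reads was taken. No row had a further solution, although for rows of usual depth solutions with very high read numbers were not counted. Reads summed over rows came to 1.05 times the mapped reads that the scale of the ratios gives. Depth was 5293237 to 10362815 mapped reads per library. Rows with a ratio of exactly 0 in at least 1 column, 449 in all, were left out, of which 355 held no read in any library. This left 11630 nuclear rows and 86 mitochondrial rows.

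Each column was centred on its median over nuclear windows, and rows were averaged in 1213 windows of 10 kb. Limma 3.58.1 in R 4.3.3 was fitted with 4 groups (strain by time, 2 columns each) and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over windows, with a threshold of 0.05. The fit had 4 residual and 4.1 prior degrees of freedom. Contrasts were eco1 against wild type at 20 and at 40 min, 40 against 20 min in each strain, and the difference of those changes. Tested on simulated data of this spread, limma called 22% of windows changed by 0.1, 72% of those changed by 0.2 and 100% of those changed by 0.4 or 0.8, with 7 false calls among 1013 unchanged windows. After the values had been seen, the same fit was made on the mean of each of the 16 chromosomes, and on the recovered reads of all 12 libraries over the mean of the wild-type 0-min libraries.

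Lists of loci fixed before the data were examined were the centromeres, the outermost 30 kb of the chromosomes, the rDNA, tRNA genes, core histone genes, ribosomal protein genes and the silent mating loci, with 2.5 kb on each side of a feature. Camera, from limma, was run on lists of at least 5 windows with a preset correlation of 0.01 and again with an estimated one. Lists of early origins, late origins, all origins and Ty elements were also fixed, and were not analysed here because no annotation of origins or Ty elements was used. The 2-micron plasmid has no rows. Profile contrast was the SD over windows of a column. Peaks were local maxima of the 5-kb running mean with a prominence of at least 0.1, matched within 10 kb, and chance matching came from 1000 random shifts. Tested on simulated profiles of 1000 rows, the peak search found 4 of 4 peaks at heights of 0.1, 0.2, 0.4 and 0.8, with 7 further peaks from noise. The data hold 11630 nuclear rows, so more peaks from noise are due there.

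Windows named in the text followed a rule set before the data were examined. At each time these were the 10 windows with the largest positive and the 10 with the largest negative difference, past the threshold and of the same sign in both replicates. At most 1 window was taken per 30 kb, the outermost 10 kb of each chromosome and the rDNA were left out, and the gene nearest the window centre gave the name. The 10 highest wild-type peaks at 20 min were named as well. At 40 min only 4 lower windows met the rule. Groups were compared by two-sided exact permutation tests where a value per library was used, and 2 libraries against 2 cannot give a p below 0.33.

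The lost region of chromosome XV was compared with 40 flanking rows, 20 kb on each side from 2 kb away, with 95% exact Poisson limits on its reads. Alternatives were windows of 5 and 20 kb, no or mean centring, equal SD, a filter on rows farther than 4 MAD from the running median of 25 rows, no rDNA or chromosome ends (20 kb), a replicate block, each library left out, an adjusted p under 0.01, and other settings of the lists and peaks. Added after the values were seen were centring within chromosomes, leaving out chromosomes I, III, V and IX or the lost region, and ratios to the wild-type 0-min libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.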

Results

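DNA content across the genome was measured by sequencing in wild-type budding yeast and in an eco1 point mutant (W216G). Eco1 is the acetyltransferase that acetylates the Smc3 subunit of cohesin during S phase. Cells were arrested in G1 with the mating pheromone α-factor and collected at 0, 20 and 40 min after release, with 2 libraries per strain and time, 12 in all. The deposited table held a log2 ratio of each 20- and 40-min library to a 0-min library for 1000-bp windows, called rows here. In such a ratio, a region that has already been copied in many cells stands above 0 and a late one below it. Reads recovered from the ratios gave 5293237 to 10362815 mapped reads per library, with a median of 461 to 890 reads per row. Counting error alone gives an SD of 0.070 to 0.089 (log2) for the ratio of a row of median depth and 0.022 to 0.028 for a window of 10 rows, and intervals below cover counting error only. Nothing in the labels says that replicates are separate cultures, so p-values measure the spread between these samples.

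At 20 min the eco1 libraries held more DNA than wild type along most of 4 chromosomes, I, III, V and IX. The mean ratio of chromosome I was 0.52 ± 0.024 (SD, n = 2) in eco1 and 0.064 ± 0.012 in wild type, a difference of 0.45 (SE 0.016) or 1.37-fold. Chromosome IX was higher by 0.19 (SE 0.0080), V by 0.11 (SE 0.0052) and III by 0.097 (SE 0.0081). Of the 24 windows of 10 kb on chromosome I, 23 had a positive difference, with a median difference of 0.54 and a 10th percentile of 0.33. The difference was positive in 43 of 44 windows on IX, 54 of 58 on V and 27 of 32 on III. By limma with Benjamini-Hochberg correction over 16 chromosomes, the adjusted p was 2e-07 for I, 4.3e-07 for V and for IX, and 2.3e-05 for III. Chromosome II was also higher, by 0.022 (limma adjusted p = 0.0145), and IV, VI, XI, XII, XV and XVI were lower relative to the genome median, by -0.055 (VI) to -0.026 (XVI) apart from XV. The value of XV, -0.061, includes the lost region described below and was -0.029 (limma adjusted p = 0.02) without its 2 windows. This test per chromosome was chosen after the values were seen. For I, III, V and IX, and for IV, VI, XI and XV, it passed in all 20 settings tried, for XII in 19 and for XVI in 18. For II it passed in 14, and did not pass without centring (0.0055, limma adjusted p = 0.60), with mean centring (0.0724), with equal SD (0.357), without either eco1 20-min library or without wild-type 20-min replicate 2. At 0 min the recovered reads of eco1 already exceeded those of wild type, by 0.13 (SE 0.013) on chromosome I and by 0.047 (SE 0.0057) on chromosome III. These come on top of the ratios above, so that over the wild-type 0-min libraries the difference at 20 min was 0.59 on I and 0.14 on III.

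**Figure D1:**
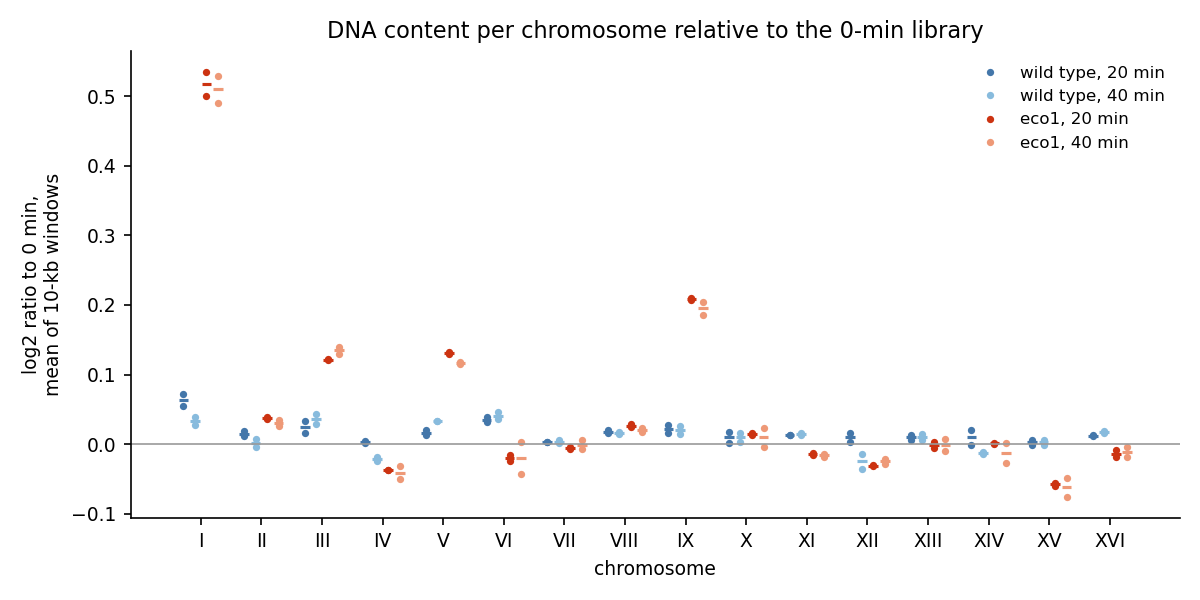
Mean log2 ratio to the 0-min library of the 10-kb windows of each chromosome, with a point for each library and a bar at the mean of the 2 replicates, for wild type and eco1 at 20 and 40 min. Chromosome I of eco1 lies at 0.52 at 20 min and 0.51 at 40 min, and IX, V and III also stand above their wild-type points.

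Which regions differed in copy number between the strains at 20 min was also asked with 10-kb windows. Of 1213 windows, 73 were higher and 23 lower in eco1 (limma, Benjamini-Hochberg adjusted p under 0.05). This balance moved with the scaling, to 60 higher and 62 lower with equal SD and 62 and 45 without centring. Equal SD divides each column by its SD over all windows, 0.136 and 0.135 in eco1 and 0.0724 and 0.0864 in wild type. On the 12 other chromosomes, each centred and without the lost region, the SDs were 0.0641 and 0.0671, and 0.0683 and 0.0837. Here and below, equal SD thus shrinks eco1 values and stretches wild-type ones because of those regions, and is not a neutral check. Of the 73 higher windows, 68 (93.2%) lay on chromosomes I, III, V and IX, which hold 158 windows. On chromosome I they included the windows of SWH1, an oxysterol-binding protein (0.70, SE 0.049), GIP4 (0.65, SE 0.044), the chromatin remodeller gene FUN30 (0.61, SE 0.061), the acetyl-CoA synthetase gene ACS1 (0.60, SE 0.047), the Ty1 element gene YAR010C (0.55, SE 0.084) and TDA8 (0.43, SE 0.040). On IX they included the windows of ICR1, a non-coding RNA upstream of FLO11 (0.41, SE 0.073), IMP21 (0.31, SE 0.042) and VHS2 (0.27, SE 0.042), and on III that of the vacuolar transporter gene ATG22 (0.27, SE 0.053). Limma adjusted p values of these 10 windows ran from 5.3e-05 (GIP4) to 0.0198 (ATG22). The other 5 higher windows, named after their values were seen, were those of YGL262W (0.26), BIG1 (0.14), YJL225C (0.25), EFM3 (0.16) and YRF1-8 (0.48), of which YGL262W, YJL225C and YRF1-8 lie at chromosome ends. When each chromosome was centred on its own median, a setting chosen after the values were seen, 0 windows were higher and 4 lower, with 172 at an unadjusted p under 0.05. The count of 96 was 27 without eco1 20-min replicate 1, 29 without its replicate 2, 190 with either eco1 40-min library left out, 40 without wild-type 20-min replicate 1 and 28 without its replicate 2.

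The deepest loss in eco1 was a stretch of chromosome XV from 1057001 to 1062000 (sacCer3). The 4 eco1 libraries of 20 and 40 min held 1 to 4 reads in its 5 rows, 0.0413% to 0.154% of the depth of the flanking rows, with an upper 95% limit (exact Poisson) of at most 0.434%. The eco1 0-min libraries held 3967 and 3459 reads there, 127% and 136% of the flanks, and the wild-type 0-min libraries 128% and 136%. Across the other 8 libraries the region held 2550 to 4397 reads. It contains YOR381W-A, the gene pair FIT2 and FIT3, which encode cell-wall proteins that retain siderophore iron, and parts of FRE3 and FRE5, of the ferric reductase family. In a scan of all rows with at least 200 reads at 0 min, the 5 rows of this region were those with under 10% of the reads due in each of the 4 eco1 columns, and 0 rows were so in the 4 wild-type columns. The 10-kb window of FRE3 was lower in eco1 by -2.19 (SE 0.033, limma adjusted p = 2.7e-09) at 20 min and by -2.09 (SE 0.033, limma adjusted p = 3.9e-09) at 40 min. The scan and the borders were chosen after the values were seen.

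**Figure D2:**
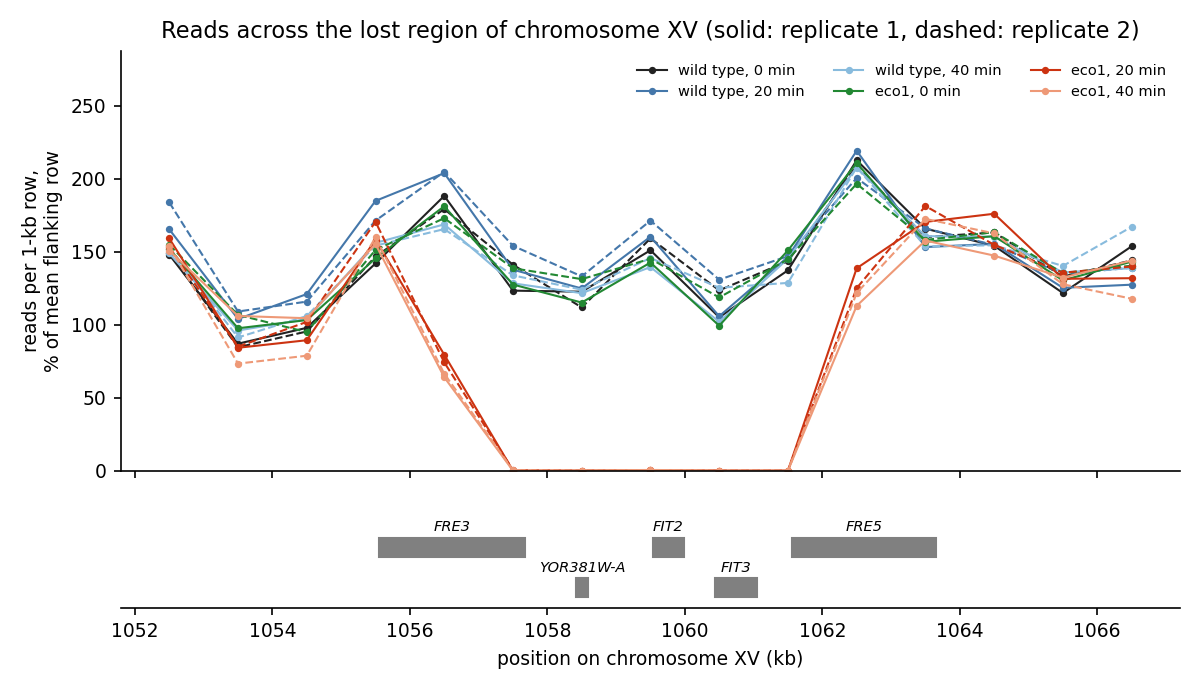
Reads per row across the lost region of chromosome XV, as a percent of the mean of 40 flanking rows, for all 12 libraries, above a map of the annotated genes. The 4 eco1 lines of 20 and 40 min drop to the floor between 1057001 and 1062000, while the other 8 stay at 127% to 147% of the flanks when averaged over the region.

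The named lower windows at 20 min, the FRE3 window (0.21) included, stood above 0 in wild type, which their choice by the difference between the strains favours. Those other than FRE3 are given here. The window of the Ty1 element gene YLR227W-B on chromosome XII stood at -0.19 ± 0.037 (SD, n = 2) in eco1 and 0.18 ± 0.054 in wild type. No filter on Ty elements was run, so reads from other Ty1 copies are not excluded in this window or in that of YAR010C. That of VMS1, which acts in mitochondrial and ribosome quality control, stood at 0.0057 ± 0.020 in eco1 and 0.26 ± 0.036 in wild type. The window of the core histone gene HTB1 stood at -0.021 ± 0.025 against 0.23 ± 0.0044, and that of the DNA ligase gene DNL4 at -0.014 ± 0.024 against 0.19 ± 0.033. The windows of YNCJ0006W, the tafazzin gene TAZ1, NOC3, the translation factor gene NIP1 and EAP1 were lower by -0.28 to -0.19. Limma adjusted p values of these 9 windows ran from 0.0033 (VMS1) to 0.0306 (HTB1 and TAZ1). After centring within chromosomes, the windows past the threshold were VMS1 (-0.22, limma adjusted p = 0.0491), FRE3, YOR385W beside it and PHO11 at the end of chromosome I, which passed only once the level of its chromosome was removed. The PHO11 window is a short remainder, from 230001 to 230218. The other named lower windows no longer passed but kept differences of -0.35 (YLR227W-B) to -0.17 (EAP1), with limma adjusted p of 0.0826 to 0.178. Centring also takes the raised chromosomes out of the windows past the threshold, which by itself raises the adjusted p of the others. The passing of these windows in the main fit may thus rest in part on the raised chromosomes.

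The tops of the wild-type profile were read in eco1 as well. The 10 highest wild-type peaks at 20 min lay nearest DCG1, VMS1, YDL007C-A, FLR1, IFM1, YNCJ0026W, SKI6, PES4, NCE103 and PRP39. At 9 of the 10, both eco1 20-min values lay below both wild-type values. The peak near VMS1 (IV, 554501) reached 0.34 ± 0.10 (SD, n = 2) in wild type and -0.029 ± 0.00025 in eco1. The peak near the drug transporter gene FLR1 (II, 254501) reached 0.33 ± 0.027 and 0.078 ± 0.023, that near IFM1 (XV, 278501) 0.33 ± 0.014 and 0.055 ± 0.015, and that near the exosome gene SKI6 (VII, 888501) 0.33 ± 0.0053 and 0.073 ± 0.043. The exception lay near DCG1 on the raised chromosome IX, at 0.35 ± 0.089 in wild type and 0.38 ± 0.0054 in eco1. Peaks chosen for their height in wild type tend to be lower in any other sample, and no test was run on these 10.

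**Figure D3:**
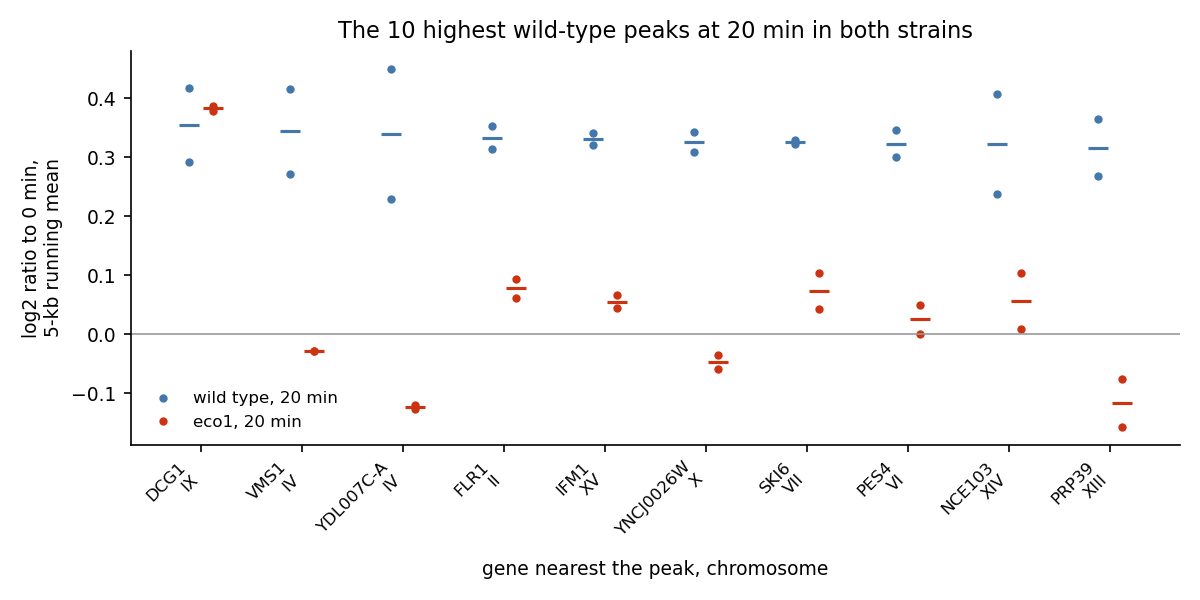
Log2 ratio to 0 min at 20 min, averaged over 5 kb, at the 10 highest wild-type peaks, with a point for each library and a bar at the mean of the 2 replicates. At 9 of the 10 peaks both eco1 points lie below both wild-type points.

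At 40 min the same chromosomes were raised in eco1. Chromosome I stood at 0.51 ± 0.028 (SD, n = 2) in eco1 and 0.033 ± 0.0084 in wild type, a difference of 0.48 (SE 0.016) or 1.39-fold, and IX was higher by 0.18 (SE 0.0080), III by 0.099 (SE 0.0081) and V by 0.084 (SE 0.0052). By limma over 16 chromosomes, the adjusted p was 1.4e-07 for I, 7.4e-07 for IX, 3.9e-06 for V and 2e-05 for III, and II was higher by 0.029 (adjusted p = 0.00556). Chromosomes IV, VI, XI, XV and XVI were lower relative to the genome median, by -0.061 (VI) to -0.020 (IV) apart from XV, at -0.065 with the lost region and -0.033 (limma adjusted p = 0.0135) without its 2 windows. Of these 10 calls, that for IV passed in 8 of 20 settings, that for XVI in 19 and that for II in 16, and the others in all 20. The call for II ended without centring (limma adjusted p = 0.478), with mean centring (0.0589), with equal SD (0.0695) and without wild-type 40-min replicate 2 (0.0507). Of 1213 windows, 45 were higher and 7 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and all 45 higher windows lay on chromosomes I, III, V and IX. The balance was 32 higher and 17 lower with equal SD, 29 and 12 without centring, and 118 and 90 without eco1 40-min replicate 1. They included GIP4 (0.64, SE 0.044), ACS1 (0.63, SE 0.047), FUN30 (0.61, SE 0.061), SWH1 (0.61, SE 0.049), the histone methylation complex gene SWD1 (0.58, SE 0.031) and TDA8 (0.37, SE 0.040) on I, and IMP21 (0.31), VHS2 (0.28), the phosphatase gene YVH1 (0.26) and the ketoglutarate dehydrogenase gene KGD1 (0.26) on IX. The named lower windows were FRE3 (-2.09), YLR227W-B (-0.28, SE 0.059), the sodium pump gene ENA1 (-0.19, SE 0.039) and the magnesium transporter gene ALR2 (-0.14, SE 0.029). After centring within chromosomes 0 windows were higher and 2 lower, FRE3 and YOR385W, with 152 at an unadjusted p under 0.05. The differences of YLR227W-B, ENA1 and ALR2 were then -0.29, -0.18 and -0.093. The count of 52 was 208 without eco1 40-min replicate 1, 32 without its replicate 2, 32 with either eco1 20-min library left out, 28 without wild-type 40-min replicate 1 and 25 without its replicate 2.

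Few windows passed the threshold between 20 and 40 min within a strain. In wild type 3 of 1213 windows fell, among them those of AVL9 (-0.23, SE 0.030) and the methionine metabolism gene SAM1 (-0.25, SE 0.032) on chromosome XII (limma adjusted p = 0.0252 for each). In eco1 the window of YJL225C, a telomeric helicase-like gene at the end of chromosome X, fell by 0.61 (SE 0.061, limma adjusted p = 0.0104), 1 of 1213. The 20- and 40-min columns of a strain and replicate share a 0-min library, which the main fit does not model. With the replicate number as a block the wild-type count was 0, but that block was common to both strains. It also ties same-numbered eco1 and wild-type columns, which are not known to be paired. No fit paired the columns within a strain and replicate, so the counts over time do not account for the shared library. At an unadjusted p under 0.05 there were 141 windows in wild type and 32 in eco1. Without any change a share of 0.05 of the 1213 windows is due, and the 32 of eco1 lie below it, as do the 30 of the strain-by-time difference below. Replicate differences of the 20- and 40-min columns had r = 0.523 in wild type and 0.181 in eco1. Such sharing makes an unpaired fit conservative over time, so few windows past the threshold do not show little change. The wild-type count was also larger under other settings, with 3 higher and 25 lower with equal SD, 0 and 10 without rDNA and chromosome ends, and 0 and 16 over the wild-type 0-min libraries. The difference between the strains in the change over time passed in 0 windows by limma, with 30 at an unadjusted p under 0.05. The wild-type count was 0 without eco1 20-min replicate 1, without its replicate 2, without wild-type 20-min replicate 1 and with either wild-type 40-min library left out, 1 without wild-type 20-min replicate 2 and 8 with either eco1 40-min library left out. The eco1 count was 0 without eco1 20-min replicate 1, its replicate 2 or eco1 40-min replicate 1, and 4 without eco1 40-min replicate 2, and the count for the strain-by-time difference was 1 without wild-type 20-min replicate 1.

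Groups of loci fixed before the data were examined were compared next. At 20 min the 24 rows around the 8 core histone genes stood at 0.023 ± 0.013 (SD, n = 2) in eco1 and 0.17 ± 0.016 in wild type, and those around tRNA genes at -0.0063 ± 0.0089 and 0.044 ± 0.0069. Rows around ribosomal protein genes stood at -0.038 ± 0.0073 in eco1 and 0.0057 ± 0.0022 in wild type, those around the 16 centromeres at 0.027 ± 0.019 and 0.040 ± 0.0046, and the outermost 30 kb of the chromosomes at 0.047 ± 0.0032 and 0.034 ± 0.024. The direction of the last 2 was not stable. The centromere difference, -0.012, was 0.017 with the MAD filter, 0.015 with 5 kb on each side and -0.093 with 1 kb. The chromosome-end difference, 0.012, was -0.039 without chromosomes I, III, V and IX, -0.0074 with equal SD and -0.0044 without centring. The 11 rows around the silent mating loci stood at -0.12 ± 0.022 and 0.077 ± 0.14. Limma's camera, run on the 4 lists of at least 5 windows, placed the 228 tRNA windows below the rest (median difference -0.026, adjusted p = 0.0274), with adjusted p = 0.60 with an estimated correlation, and 10 of them were higher and 7 lower in eco1 over all windows, 10 and 6 adjusted over the list alone. With equal SD these counts were 8 and 24 over all windows and 11 and 30 over the list alone, and without centring 9 and 16, and 9 and 19. For ribosomal protein genes (8 higher and 1 lower of 123 windows) the camera adjusted p was 0.141, for centromeres (2 higher and 1 lower of 16) 0.662 and for chromosome ends (9 higher and 3 lower of 103) 0.662. Adjusted over the list alone, the counts were 8 and 1, 2 and 1, and 11 and 6. Leaving out an eco1 40-min library, which does not enter these differences, turned the balance of ribosomal protein and tRNA windows toward lower ones. Their median differences stayed at -0.023 and -0.026. Without eco1 20-min replicate 1 or its replicate 2 the ribosomal protein median was -0.027 or -0.021. The tRNA call ended without eco1 20-min replicate 1 (camera adjusted p = 0.0589), without wild-type 20-min replicate 1 (0.0927), with the MAD filter (0.104) and over the wild-type 0-min libraries (0.532). The histone and silent-locus values, from 2 libraries against 2, could not pass an exact permutation test, which cannot go below p = 0.33.

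At 40 min camera placed ribosomal protein, tRNA and chromosome-end windows below the rest, each with an adjusted p of 0.0153. Their median differences were -0.021, -0.023 and -0.039, and the calls were lost with an estimated correlation (adjusted p = 0.254, 0.327 and 0.254). Without chromosomes I, III, V and IX, a setting chosen after the values were seen, the chromosome ends passed with an estimated correlation as well (median difference -0.072, adjusted p = 0.0411). Of the ribosomal protein windows 3 were higher and 0 lower, of the tRNA windows 10 and 1, and of the chromosome-end windows 3 and 3, where adjusting over the list alone gave 3 and 0, 10 and 1, and 5 and 9. With equal SD the counts were 1 and 1 (ribosomal protein), 5 and 4 (tRNA) and 1 and 7 (ends) over all windows. The balance turned toward lower windows in each of these lists without eco1 40-min replicate 1, where the median differences were -0.030, -0.036 and -0.030. Without its replicate 2 they were -0.011, -0.0074 and -0.046. For the centromeres, with 1 window higher and 0 lower and the same counts adjusted over the list alone, the adjusted p was 0.0982. The centromeres passed with equal SD (camera adjusted p = 0.00242), after centring within chromosomes (0.00273) and without chromosomes I, III, V and IX (0.00799), and in none of the 3 with an estimated correlation (0.151, 0.159 and 0.111). Row means were 0.057 ± 0.073 (SD, n = 2) in eco1 and 0.097 ± 0.0096 in wild type at centromeres, -0.014 ± 0.047 and 0.037 ± 0.011 at ribosomal protein genes, and 0.013 ± 0.057 and 0.056 ± 0.026 at tRNA genes. They were 0.025 ± 0.0055 and 0.053 ± 0.022 at chromosome ends, 0.029 ± 0.10 and 0.083 ± 0.00087 at histone genes, and 0.027 ± 0.38 and 0.33 ± 0.22 at the silent mating loci. Without wild-type 40-min replicate 2 the count of lists past the threshold was 0, and without eco1 40-min replicate 2 it was 1, the chromosome ends (camera adjusted p = 0.0036, and 0.462 with an estimated correlation). Without eco1 40-min replicate 1 the chromosome ends no longer passed (0.096) and the centromeres did (0.0464, and 0.247 with an estimated correlation), and with ends of 15 kb the chromosome-end call was lost (0.409). That call also ended without centring (camera adjusted p = 0.0876) and without rDNA and chromosome ends (0.148). The latter setting removes the outer 20 kb of the list itself and leaves 64 of its 103 windows, so this loss says little about the call. The tRNA call ended with the MAD filter (0.0506) and over the wild-type 0-min libraries (0.573), and the ribosomal protein call over the wild-type 0-min libraries (0.112).

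The ribosomal DNA, the tandem array of rRNA genes on chromosome XII, had a lower ratio in eco1 than in wild type at 20 min. Its 5 kept rows averaged -0.23 ± 0.088 (SD, n = 2) in eco1 and 0.056 ± 0.0058 in wild type, a difference of -0.29. The 2 rows that carry nearly all of its reads, at 459001 and 460001, stood at -0.29 ± 0.0046 in eco1 and 0.091 ± 0.071 in wild type, and held 58.7 and 59.3 times the median row in the eco1 20-min libraries against 73.2 and 73.5 times at 0 min. At 40 min the rDNA rows averaged -0.11 ± 0.037 in eco1 and 0.040 ± 0.33 in wild type, a difference of -0.15, which was 0.086 without wild-type 40-min replicate 2 and -0.38 without its replicate 1. These means give each row the same weight. The row at 481001 held only 1 to 10 reads per library and stood at -0.40 and 1.06 in the wild-type 40-min libraries. In the 2 high-copy rows the difference at 40 min was -0.22, with -0.11 and -0.31 in the eco1 libraries and -0.084 and 0.10 in the wild-type ones. The mitochondrial genome, 86 rows, stood at -0.29 ± 0.097 in eco1 and 0.28 ± 0.071 in wild type at 20 min, and at -0.32 ± 1.15 and 0.55 ± 0.46 at 40 min. These are means over rows, and by summed reads the fall in eco1 was smaller. The mitochondrial share of reads went from 3.31% and 3.59% at 0 min to 3.15% and 3.34% at 20 min in eco1, and from 2.34% and 2.27% to 2.79% and 2.61% in wild type, so that it stayed higher in eco1. Exact permutation tests, two-sided with n = 2 per group, gave p = 0.33 for both at 20 min, the smallest p they can give. Since the eco1 20- and 40-min libraries lack a region that their 0-min libraries hold, the 2 kinds of library differ in DNA that replication does not change, and the copy number of the rDNA is not excluded from that.

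**Figure D4:**
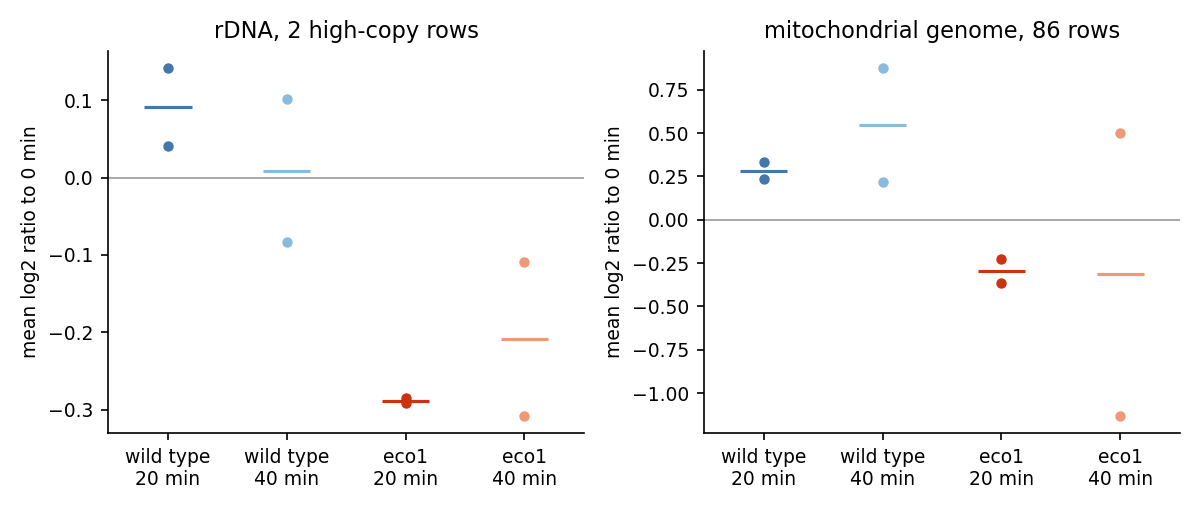
Mean log2 ratio to 0 min of the 2 high-copy rDNA rows (left) and the 86 mitochondrial rows (right), with a point for each library and a bar at the mean of the 2 replicates. Both eco1 20-min points lie below 0 in each panel, and the 2 eco1 40-min libraries stand apart at 0.50 and -1.13 in the mitochondrial rows.

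Profiles of the strains were compared across the 1213 windows, as a description. At 20 min the contrast of the profile, its SD over windows, was 0.135 ± 0.00076 (SD, n = 2) in eco1 and 0.0794 ± 0.0099 in wild type, and at 40 min 0.137 ± 0.015 and 0.0748 ± 0.019. The exact permutation p was 0.33 at both times. Without chromosomes I, III, V and IX the difference of 0.0557 at 20 min became 0.024, and that of 0.0619 at 40 min became 0.0318, with the lost region still included. With those chromosomes and the windows of the lost region left out and each chromosome centred, chosen after the values were seen, the difference at 20 min turned the other way, with SDs of 0.0641 and 0.0671 in eco1 and 0.0683 and 0.0837 in wild type. At 40 min the SDs were then 0.0518 and 0.086 in eco1 and 0.0598 and 0.0853 in wild type. The profiles of the strains followed each other little across windows, which are not independent replicates, with r = 0.0972 at 20 min and r = 0.0949 at 40 min. At 40 min r was 0.299 without eco1 replicate 2 and -0.094 without eco1 replicate 1. The slope of eco1 on wild type by orthogonal regression was 14.7 and 15.3, but it ran from 2.97 to 63.1 at 20 min and from -1482 to 49.5 at 40 min over the 33 settings tried, so its size and sign are not stable.

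Local maxima of the smoothed profile were compared last, without an annotation of origins. At 20 min wild type had 294 and eco1 510, and 241 wild-type peaks (82.0%) had an eco1 peak within 10 kb, against a mean of 72.5% for randomly shifted positions (upper limit of their central 95%, 77.2%). Between the wild-type replicates the share was 87.7%, with 75.5% for shifted positions. With a prominence of 0.2, 77 of 123 wild-type peaks (62.6%) were matched, against 28.6% by chance. At 40 min wild type had 479 peaks and eco1 343, and 262 (54.7%) were matched, against 52.7% by chance, with an upper limit of 55.9%. The share at 40 min was above its upper limit by chance without eco1 40-min replicate 2 (72.7% against 65.4%), without wild-type 40-min replicate 1 (57.5% against 55.7%) or its replicate 2 (57.0% against 55.9%), at a prominence of 0.05 (90.5% against 90.2%) and with the MAD filter (53.0% against 52.2%).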

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

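All tests of explanations in this part were chosen after the result they address was seen.

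The ratio to 0 min differed between eco1 and wild type in 96 windows of 10 kb at 20 min and in 52 at 40 min, and in 11 and 10 of 16 chromosomes. Without a test, every eco1 library moved one way and every wild-type library the opposite way at 20 min in the rDNA (a difference of -0.29 over its rows and -0.38 in its 2 high-copy rows), the mitochondrial genome (-0.58 as a mean over rows), rows around tRNA genes (-0.051) and rows around ribosomal protein genes (-0.044). These differences in sign were not tested, and in the rows around tRNA genes 1 eco1 library lay within rounding of 0. Around ribosomal protein genes the opposite sign depends on the median centring, since without centring the wild-type libraries also lay below 0 (-0.0089 and -0.0063), and around tRNA genes both eco1 libraries lay above 0 (0.0095 and 0.014) with 5 kb on each side. In the eco1 0-min libraries, which enter the ratios only as denominators, chromosome I stood 0.13 and chromosome III 0.047 above the wild-type 0-min libraries (limma adjusted p = 2.3e-05 and 7.8e-05).

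The first pattern is the gain of chromosomes I, III, V and IX together with the loss of the FRE3 to FRE5 region in the eco1 20- and 40-min libraries. Replication timing cannot account for the loss, since the region held at most 0.154% of the flanking depth where an uncopied region keeps its single copy. On chromosome I even the 10th percentile of its windows was 0.28, which argues against a gain confined to early-copied stretches. Early copying along the full chromosome would also give an even gain, and this test cannot exclude it. On III, V and IX, with 10th percentiles down to -0.046 on III and of 0.091 and 0.10 on IX, the gains are too small for this test. On these 3 chromosomes timing cannot be told apart from extra copies. The eco1 0-min libraries cannot come only from cells with the chromosome I content of the wild-type 0-min libraries, as their chromosome I stood 0.13 above it. Chromosome I content does not show the genotype at eco1, so wild-type cells with more of chromosome I are not excluded. The eco1 0-min libraries also cannot be a single mixture of cells like the wild-type control with the later cells. The lost region gave a share of later-type cells of 0.343% (SE 4.44) and chromosome I a share of 18.4% (SE 1.90). The eco1 0-min and later libraries thus differ in DNA that replication does not change, and such differences can enter every eco1 ratio. That the 0-min libraries came from another isolate or culture than the 20- and 40-min libraries is a candidate explanation that stays open. Whether the mutation of eco1, a gene needed for sister chromatid cohesion, led to the raised chromosomes was not tested, because each strain is a single genotype.

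The second pattern is the low ratio of the eco1 20-min libraries at wild-type peaks. At 120 peaks chosen in wild-type 20-min replicate 1 on the 12 other chromosomes, wild-type replicate 2, which had no part in the choice, averaged 0.13 against 0.0020 and 0.0053 in the eco1 20-min libraries, which argues against choice of the peaks as the whole cause. With the wild-type 0-min library of replicate 2 as denominator the eco1 20-min mean rose to 0.061 ± 0.016 (SD, n = 2), while the eco1 0-min libraries themselves stood at 0.044 and 0.065 over it. The 0-min libraries may thus account for part of the difference, and this explanation cannot be told apart from a lower level at the peaks because it leaves eco1 about midway between its own ratio and the 0.13 of wild type. A later S phase in eco1 also stays open, since the 40-min mean at these peaks was -0.011 with replicates at 0.041 and -0.063, and no flow cytometry or other measure of S-phase progress was analysed here.

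The third pattern is the opposite course of the eco1 40-min libraries, whose profiles on the 12 other chromosomes had r = -0.297, against 0.560 between the eco1 20-min libraries. Both lacked the FRE3 to FRE5 region (at most 0.12% of the flanking depth), which excludes a swap with a wild-type library, and the library labelled 20 min replicate 2 had r = -0.098 with 40 min replicate 1, which argues against a swap of the labels within replicate 2. Replicate 2 of 40 min had r = 0.475 with 20 min replicate 1, a library with which it shares no denominator. Cells still at the stage of the 20-min samples could give this, but other values differed from that stage. At the 120 wild-type peaks it stood at -0.063, against 0.0020 and 0.0053 in the eco1 20-min libraries. Its mitochondrial rows stood at -1.13 against -0.23 and -0.36. Its r with the wild-type 20-min libraries was -0.175 and -0.104, against 0.165 and 0.049 for eco1 20-min replicate 1 and 0.165 and 0.073 for replicate 2. Replicate 2 of 40 min is also the eco1 library with the fewest mapped reads (5293237), and a cause in its culture or its library was not tested apart.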

How the results depend on the processing

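Centring within chromosomes, leaving out chromosomes or the lost region, ratios to the wild-type 0-min libraries, the high-copy rDNA rows alone, tests per chromosome and the crossed block were chosen after the data were seen, and the other settings before. Where a value moved, the cause was not tested unless given. Counts of windows, eco1 against wild type, were 96 at 20 min and 52 at 40 min. They were 4 and 2 after centring within chromosomes, 3 and 2 without chromosomes I, III, V and IX, 3 and 2 over the wild-type 0-min libraries with centring within chromosomes, and 34 and 24 at an adjusted p under 0.01, and the 40-min count was 112 over the wild-type 0-min libraries. Centring within chromosomes removes the level of each chromosome by construction, while leaving out chromosomes I, III, V and IX removes only theirs. Equal SD shrinks eco1 values and stretches wild-type ones, since the raised chromosomes and the lost region add to the eco1 SD. The 23 lower windows at 20 min and the 7 at 40 min all lay on other chromosomes. Without the 4 chromosomes 3 and 2 lower windows passed. Leaving these chromosomes out also takes away 68 of the 73 higher windows at 20 min and all 45 at 40 min. Fewer small p-values by themselves raise the Benjamini-Hochberg adjusted p of the remaining windows. The VMS1 difference at 20 min went from -0.25 (limma adjusted p = 0.0033) to -0.24 (limma adjusted p = 0.025). How much of the loss came from the adjustment was not tested. Besides FRE3 and YOR385W, the few windows were VMS1 and PHO11 (centred), VMS1 (without the chromosomes) and YAR061W (over wild type, centred). Counts of chromosomes, 11 and 10, stayed at 9 to 12 and 7 to 12 over the settings tried. With 1 library left out the ranges were 27 to 190 and 25 to 208, and the lone library is then assumed to vary like the other groups.

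For wild type 40 against 20 min, with 3 windows, the count was 0 with 5-kb windows, 20-kb windows, centring within chromosomes or an adjusted p under 0.01, 28 with equal SD, 10 without rDNA and chromosome ends, 16 over the wild-type 0-min libraries, 12 with those and centring, and 0 to 8 with 1 library left out. For eco1 40 against 20 min, with 1 window, it was 0 with 20-kb windows, equal SD, the MAD filter, no rDNA and chromosome ends, either ratio to wild type or an adjusted p under 0.01, and 0 to 4 with 1 library left out. The strain-by-time count ranged from 0 to 1 (limma, 30 at an unadjusted p under 0.05). Lists past the threshold, 1 at 20 min and 3 at 40 min, were 0 and 0 with an estimated correlation, 0 and 1 over the wild-type 0-min libraries, 0 at 20 min with the MAD filter, 4 at 40 min with equal SD, after centring within chromosomes or without chromosomes I, III, V and IX, 2 at 40 min without centring, with the MAD filter, without rDNA and chromosome ends or with ends of 15 kb, and 0 to 1 and 0 to 3 with 1 library left out. Leaving out the chromosome ends removes rows of the chromosome-end list itself.

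Replicate numbers are not known to pair the samples: residual profiles of same-numbered eco1 and wild-type columns had r = 0.0949 at 20 min and -0.147 at 40 min. Within a strain the 20- and 40-min columns share a 0-min library, and r was 0.523 in wild type and 0.181 in eco1. With the number as a block common to both strains, the window counts were 69 and 41, the wild-type 40 against 20 min count was 0, and the share of matched peaks at 40 min, by same-numbered pairs, was 79.8%. Single libraries of 40 min held 416 and 730 peaks in eco1 and 444 and 671 in wild type, against 343 and 479 in the means. Chance matching was not computed for these pairs, so 79.8% does not show closer profiles than 54.7%. A block for each strain and replicate, which would follow the shared 0-min libraries, was not fitted. With the wild-type numbers crossed the block gave 140 and 72 windows.

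The contrast difference, 0.0557 at 20 min and 0.0619 at 40 min, was 0.0398 and 0.0431 with the MAD filter, 0.0364 and 0.0436 with row medians, 0.0204 and 0.0301 after centring within chromosomes, 0.024 and 0.0318 without chromosomes I, III, V and IX, and 0.037 and 0.0408 without the lost region. At 20 min it was also 0.067 with 5-kb windows and 0.0675 over the wild-type 0-min libraries. With 1 library or 1 chromosome left out it ranged from 0.0342 to 0.0627 and from 0.042 to 0.0752. Equal SD fixes this value and was not run for it. The correlation at 20 min (0.0972) was 0.181 with the MAD filter, 0.168 with row medians, 0.0483 and 0.193 with 5-kb and 20-kb windows, 0.0107 after centring within chromosomes, 0.0407 without the 4 chromosomes, 0.221 over the wild-type 0-min libraries, 0.156 without the lost region and 0.0639 to 0.155 with 1 library or chromosome left out. At 40 min (0.0949) it was 0.150 with the MAD filter, 0.119 with row medians, 0.0264 and 0.175 with 5-kb and 20-kb windows, -0.0220 after centring within chromosomes, -0.000504 without the 4 chromosomes, 0.276 over the wild-type 0-min libraries, 0.123 without the lost region and -0.094 to 0.299 with 1 library or chromosome left out.

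Matched peaks, 82.0% and 54.7%, were 94.3% and 90.5% at a prominence of 0.05, 62.6% and 8.53% at 0.2, 59.9% and 14.8% with a 10-kb running mean, 52.0% and 28.2% with matching within 5 kb, 70.2% and 29.1% with equal SD, and 77.9% to 86.1% and 57.0% to 89.4% with 1 library left out. A share of matched peaks falls with fewer peaks or a shorter distance by construction. The rDNA difference at 20 min, -0.29, was -0.38 in its 2 high-copy rows alone and stayed between -0.35 and -0.22 with 1 library left out. At 40 min it ranged from -0.38 to 0.086. Of 590 alternatives for the 34 named windows, 413 kept direction and side of the threshold, 173 kept the direction but no longer passed, and 4 reversed: TDA8 at -0.11 and -0.10 (20 min) and -0.17 and -0.16 (40 min) with centring within chromosomes, of the deposited ratios and of those to wild type. Of 162 alternatives for the list means, 125 moved by less than the replicate SD. The part of the planned filter on Ty elements and LTRs was not run. Counting error in a ratio has an SD of 0.070 to 0.089 per row and 0.022 to 0.028 per 10-kb window, a sizeable part of the median limma SD of 0.040 per window.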

Other observations

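The mitochondrial share of reads was 2.34% and 2.27% in the wild-type 0-min libraries and 3.31% and 3.59% in the eco1 0-min libraries. It was 2.79% and 2.61% in wild type and 3.15% and 3.34% in eco1 at 20 min, and 2.46% and 3.30% against 4.35% and 2.11% at 40 min. The widest 95% binomial (Wilson) interval among these shares spans 3.28% to 3.31%. Every eco1 library of 0 and 20 min held a higher mitochondrial share than every wild-type library of those times.

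Profiles of single libraries were compared on the 12 chromosomes other than I, III, V and IX, with each chromosome centred and without the windows of the lost region. The wild-type libraries had r = 0.411 between replicates at 20 min and 0.386 at 40 min. Replicate 1 of eco1 at 40 min had r = 0.362 and 0.40 with the wild-type 40-min libraries, while replicate 2 had r = -0.303 and -0.239 with them.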
